A study of Penaeus vannamei with 48 samples.

How the data were processed

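Gill (a filament of the fourth gill) and intestine of Pacific white shrimp from 3 aeration levels were measured by RNA-seq in 48 libraries, 24 per tissue and 8 per tissue and aeration level. Per the labels' protocols, libraries were made from 250 ng of RNA with a stranded poly(A) ligation kit. Trimmomatic 0.39, STAR 2.7.8a and HTSeq 2.0.5 are named in the submitters' processing notes, without their settings. The genome build and annotation behind the table are not given in the sources used here. The deposited table holds the authors' raw read counts, as whole numbers, for 39654 rows, most named by a RefSeq transcript accession (36329), with 2013 tRNA rows, 1275 rows named by a gene identifier and 37 mitochondrial rows. Of these, 17032 were 0 in all libraries. Library totals were summed over all 39654 rows, which hold no summary row of unassigned reads.

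Rows are transcripts, not genes, so reads that fit several transcripts of a gene could be split or dropped by the counting. Among rows matched to the reference, 70.7% of the 5114 rows of genes with several rows were 0 in all libraries, against 18.8% of the 7045 rows of genes with 1 row. Symbols were taken from a RefSeq gene table of assembly ASM4276789v1 (GCF_042767895.1), matched by accession without the version. It matched 12159 rows (149 with the same version), of which 2632 had a symbol other than a locus number or tRNA name. No coordinates of that assembly were used. All 48 columns were matched to samples by their labels. No libraries were duplicates by a chi-square comparison of counts: the smallest median statistic over its null value was 23.2.

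Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with the group, estimateDisp, robust glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a transcript is from edgeR's quasi-likelihood test unless another tool is named. Each tissue was fitted on its 24 libraries with 1 coefficient per aeration group, leaving 11769 transcripts in gill (1116 with a symbol) and 11645 in intestine (1114). The tissue contrast and the difference between tissues in the effect of low against high aeration used all 48 libraries and 13854 transcripts. Per-library levels are log2 CPM with a prior count of 2. Levels of the sets of 454 intestine, 371 gill and 75 other transcripts below, dyl included, are instead log2 CPM of the nuclear counts without TMM. A small constant was added to each of these counts, so a transcript without a count also has a level. The median biological coefficient of variation was 57.5% in gill and 59.9% in intestine. The median SE of a log2 fold change at low against high aeration was 0.41 in gill and 0.43 in intestine, and 0.75 for the difference between tissues, which limits what small changes can be seen.

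Gene lists were tested with limma 3.58.1's camera on voom values, with a preset correlation between genes of 0.01 and adjustment over 22 lists, and again with the correlation estimated from the data and with fry, which tests whether a list moves 1 way on balance. A list needed at least 3 tested members. The 27 lists first planned matched words in gene descriptions, which the reference table does not hold. They could not be run, and 22 lists matched on symbols were written in their place after the table had been seen and before any test. Markers of haemocytes, muscle and hepatopancreas and genes of the hypoxia-inducible factor pathway had no symbols and were not analysed here. The lists cover mitochondrially encoded proteins, nuclear oxidative phosphorylation, glycolysis, TCA cycle, cytosolic and mitochondrial ribosomal proteins, proteasome, endoplasmic reticulum folding, chaperones, antioxidant enzymes, ion transport, replication and mitosis, ecdysteroid signalling and cuticle, clock, neuronal markers, autophagy, TOR and insulin signalling, lipid metabolism, aminoacyl-tRNA synthetases, splicing, secretory pathway and immune signalling.

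The rule for named genes was set before the data were examined, as were the designs and most alternatives. It takes the transcripts with the smallest p past the threshold, or the 5 with the smallest p where fewer than 5 pass, and 2 members per list. For the tissue contrast it takes the 5 largest changes each way among transcripts with mean log2 CPM above 5. A transcript with a symbol counted as described. SIFa and dyl were chosen after their values were seen. The tests were checked on simulated data drawn from these libraries: with 50 transcripts at each fold, edgeR recovered 0% at 1.5-fold, 16% at 2-fold, 56% at 4-fold and 82% at 8-fold in gill, and 2%, 22%, 60% and 82% in intestine. There transcripts and libraries varied independently, and changes were placed only in transcripts with mean log2 CPM above 0. The shares therefore do not measure recovery in the real libraries, which share structure and tanks. Camera called a shifted list and 0 of 99 lists left as they were, in simulated data whose transcripts varied independently of each other. In 100 regroupings of the real libraries camera called a median of 6 to 7 of 22 lists in gill and 4 to 5 in intestine.

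Alternatives were DESeq2 1.42.0 as the test and its size factors in edgeR, limma voom with sample weights, no filter on low counts, only the 2 groups compared, the replicate number as a block, counts of consecutive numbers summed, surrogate variables from sva 3.50.0 (number set with 20 permutations) and each library left out in turn. In fits of both tissues the block was the aeration group and number together, which pairs gill and intestine libraries of the same number. Added after seeing the data were fits without gill medium 4, without 5 gill libraries holding transcripts of another library, without gill low 4, high 5 and high 6, without gill high 1 and high 2, without these 9 gill libraries together, without intestine low 3, low 8, medium 3 and medium 4, and without the mitochondrial rows, and DESeq2 on the transcripts that edgeR tested, without its own filter. For each count of calls 100 regroupings of the libraries were drawn (40 for DESeq2), and in gill 100 more that kept consecutive label numbers together were drawn after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.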

Results

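Pacific white shrimp (*Penaeus vannamei*, a farmed marine prawn) were kept for 42 days in green water, in which suspended algae add oxygen by day and use it by night, at 3 levels of aeration. Air was supplied at 0.25 cubic feet per second (low), 0.35 (medium) or 0.7 (high), with 4 tanks of 800 L per level and 35 shrimp of 1.99 ± 0.06 g stocked in each at 15 ppt salinity. At the end 2 shrimp per tank were taken, so each level has 8 shrimp, and gill and intestine of each were sequenced as stranded mRNA libraries. The 48 libraries fall into 6 groups of 8. The labels do not say which shrimp shared a tank, so the p-values treat 8 shrimp as independent where 4 tanks were. Total counts ran from 25404217 to 42549945 in gill and from 24342496 to 44601172 in intestine. Mitochondrial transcripts took 14% to 41% of the counts in gill and 18.6% to 45.3% in intestine. Within these shares 1 mitochondrial ribosomal RNA took 8.1% to 31.3% of the counts in gill and 13% to 36.5% in intestine.

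Every value belongs to 1 transcript, named by the symbol of its gene where the reference gives one and otherwise by its identifier. Levels are log2 CPM (counts scaled to library size) as mean ± SD over 8 libraries, and changes are log2 fold changes with their standard error (SE). Gill libraries spread widely within each aeration group: the first principal component of gill held 29.5% of the variance, with 4.3% of it between aeration groups, and the second held 22.7%, with 25.9% between groups. In intestine the first held 32%, with 6.9% of it between groups.

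**Figure D1:**
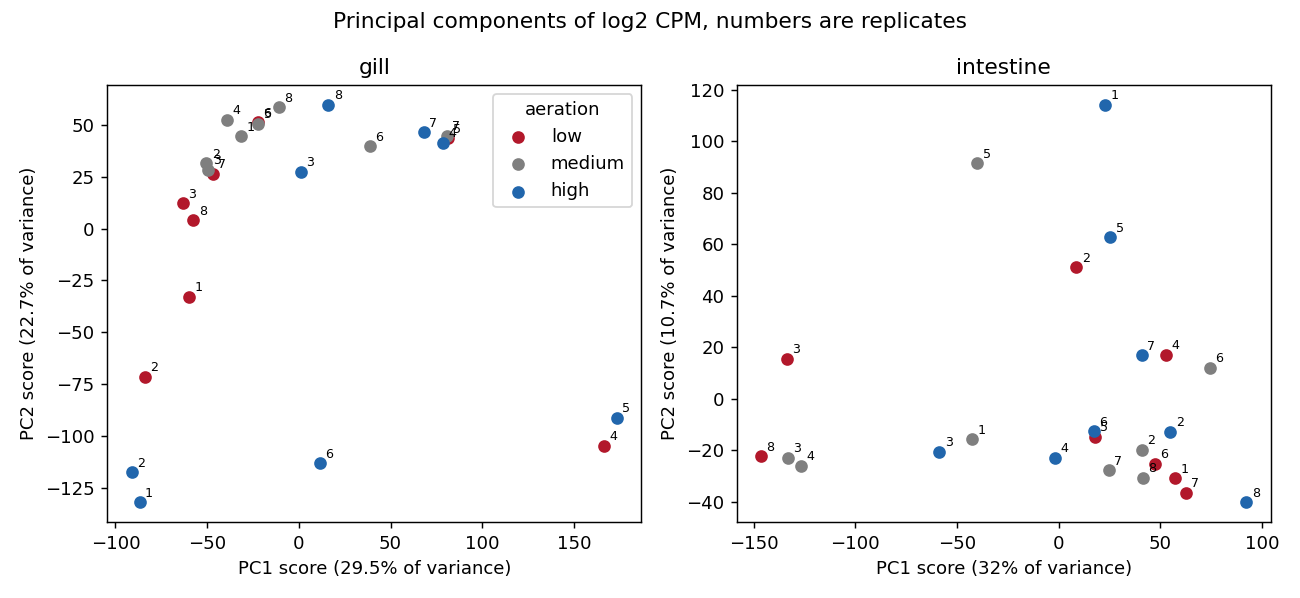
Scores of the 24 gill libraries (left) and 24 intestine libraries (right) on the first and second principal components of log2 CPM, in arbitrary units, coloured by aeration and numbered by replicate. In gill, low 4 and high 5 lie apart on the first component, which holds 29.5% of the variance with 4.3% of that between aeration groups.

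Several gill libraries stood apart in ways that bear on the gene groups. The library labelled gill medium 4 held intestine transcripts. For 454 transcripts abundant in intestine, chosen without it and intestine medium 4, its median was 5.01 log2 CPM of nuclear counts. Their median was -6.11 to -5.16, the level without a count, in the other gill libraries and 4.56 to 7.59 in intestine. In gill medium 4, 371 gill transcripts had a median of 4.89, against 5.69 to 7.52 in the other gill libraries and -5.64 to -1.44 in intestine. In gill low 4 and high 5, 75 transcripts held 26.105% and 27.721% of the nuclear counts, against at most 0.018% in 21 other gill libraries. They were chosen as abundant in both and far lower in the 21 others, so this contrast follows from the choice. Both symbols among these 75 belong to dyl (dusky-like), a membrane protein of cuticle-forming epithelium in insects. Its level was 6.01 log2 CPM or more in low 4 and high 5 and at most -5.16, the level without a count, in the 21 others. Gill high 6, which was set aside by name in that choice, held the same 75 transcripts at a median log2 ratio of -1.48 to high 5. Gill high 1 and high 2 had the lowest second component scores of gill (-131.9 and -117.4) and mitochondrial shares of 33.8% and 41%, against 18.9% to 25.7% in the other high libraries. Gill low 1, medium 6, high 3 and high 6 held nearly all abundant transcripts of another gill library. With medium 4, low 4, high 1, high 2 and high 5 these make 9 gill libraries that stood apart. In intestine, low 3, low 8, medium 3 and medium 4 stood apart on the first component (-133.6, -146.3, -133.1 and -126.5), and the 454 intestine transcripts had medians of 5.34, 4.56, 5.3 and 5.5 in them, against 6.74 to 7.59 in the other intestine libraries.

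**Figure D2:**
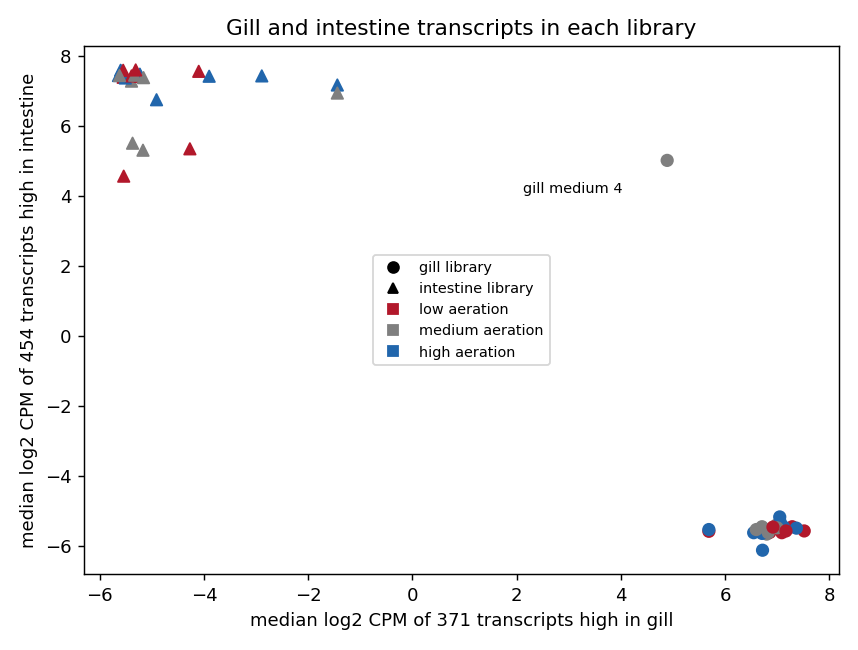
Median log2 CPM of 371 transcripts high in gill (horizontal axis) and of 454 transcripts high in intestine (vertical axis), 1 point per library, circles for gill and triangles for intestine, coloured by aeration. Both sets were chosen on all libraries but gill medium 4 and intestine medium 4, so the separation of the libraries used follows from the choice. The library labelled gill medium 4 lies at 4.89 and 5.01, high on both axes.

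The comparison of gill with intestine gives the level of each gene group in each tissue. Of the 7 transcripts in the ecdysteroid and cuticle list, 5 were higher in gill and 1 was lower, though the list did not pass camera (adjusted p = 0.131). The cytochrome P450 phtm (phantom), an enzyme of ecdysteroid synthesis in arthropods, reached 8.31 ± 0.88 log2 CPM in gill and -0.08 ± 2.38 in intestine (n = 24 each), a change of 7.11 (SE 0.65, adjusted p = 5.09e-13), with all 24 of 24 gill libraries above the intestine median. Counts of the chitinase Cht6 lay between 33 and 9430 in gill, and were 0 in 16 of 24 intestine libraries and at most 35 in the rest. Intestine in turn carried SIFa, which encodes the neuropeptide SIFamide, at 598 to 15957 counts. SIFa was at 0 in 22 of 24 gill libraries, with 770 counts in gill medium 4 and 4 counts in the 1 remaining.

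Many transcripts of energy metabolism differed between the tissues, as did 9547 of 13854 transcripts in all. Of the energy lists, camera called nuclear oxidative phosphorylation alone, and none with an estimated correlation. Of 41 nuclear genes of oxidative phosphorylation, 35 were lower in gill and 1 was higher, with a median log2 change of -0.87. COX7B, a subunit of cytochrome c oxidase, changed by -2.51 (SE 0.29, adjusted p = 1.79e-10, 24 of 24 libraries) and ND-13A, a subunit of complex I, by -1.95 (SE 0.25, adjusted p = 3.36e-09). Of 13 proteins encoded in mitochondrial DNA, 12 were lower in gill, with ND6 at -1.41 (SE 0.18). Hexokinase Hex-A was lower in gill by -3.84 (SE 0.43), at low counts in both tissues (0 to 29 in gill and 25 to 283 in intestine). Malate dehydrogenase Mdh1 was higher in gill by 1.42 (SE 0.12). The electron transfer flavoprotein genes Etf-QO and Etfb, which pass electrons from fatty acid oxidation to the respiratory chain, were lower in gill at -2.44 (SE 0.29) and -1.68 (SE 0.22), as was the triglyceride lipase bmm (brummer) at -3.02 (SE 0.32).

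In the proton pump and ion transport list 6 of 9 transcripts were higher in gill and 2 lower, though the list did not pass camera (adjusted p = 0.314). Its members include the vacuolar proton pump subunits Vha44 at 2.38 (SE 0.33) and VhaSFD at 1.84 (SE 0.32). Of 42 transcripts for cytosolic ribosomal proteins 24 were higher in gill and 1 lower, with a median of 0.36 and RpL31 at 0.62 (SE 0.14). Mitochondrial ribosomal proteins had 2 of 53 higher and 20 lower, and aminoacyl-tRNA synthetases 5 of 14 higher and 5 lower. Of 21 transcripts of TOR and insulin signalling 13 were lower in gill and 4 higher. Autophagy genes were lower in gill for 5 of 7, including Atg101 at -1.65 (SE 0.2). Among clock genes, 2 of 4 were lower in gill, namely cry at -1.32 (SE 0.19) and tim at -1.45 (SE 0.35).

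Among abundant transcripts with a symbol, the largest differences toward gill were Cont (contactin, a septate junction protein) at 3.85 (SE 0.24), sky at 3.42 (SE 0.34), the tyrosine-degrading enzymes hgo at 2.95 (SE 0.54) and Faa at 2.74 (SE 0.36), and the phosphatase Pez at 2.5 (SE 0.26). Toward intestine they were senju at -4.26 (SE 0.27), the synaptic vesicle GTPase Rab3 at -3.42 (SE 0.24), the actin regulator ena at -3.41 (SE 0.22), Pect at -3.37 (SE 0.25) and mspo at -3.13 (SE 0.46). All 10 had adjusted p of 5.7e-06 or less, and 18 to 24 of 24 gill libraries lay beyond the intestine median. For mspo, gill medium 4 held 15966 counts and no other gill library more than 1460.

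**Figure D3:**
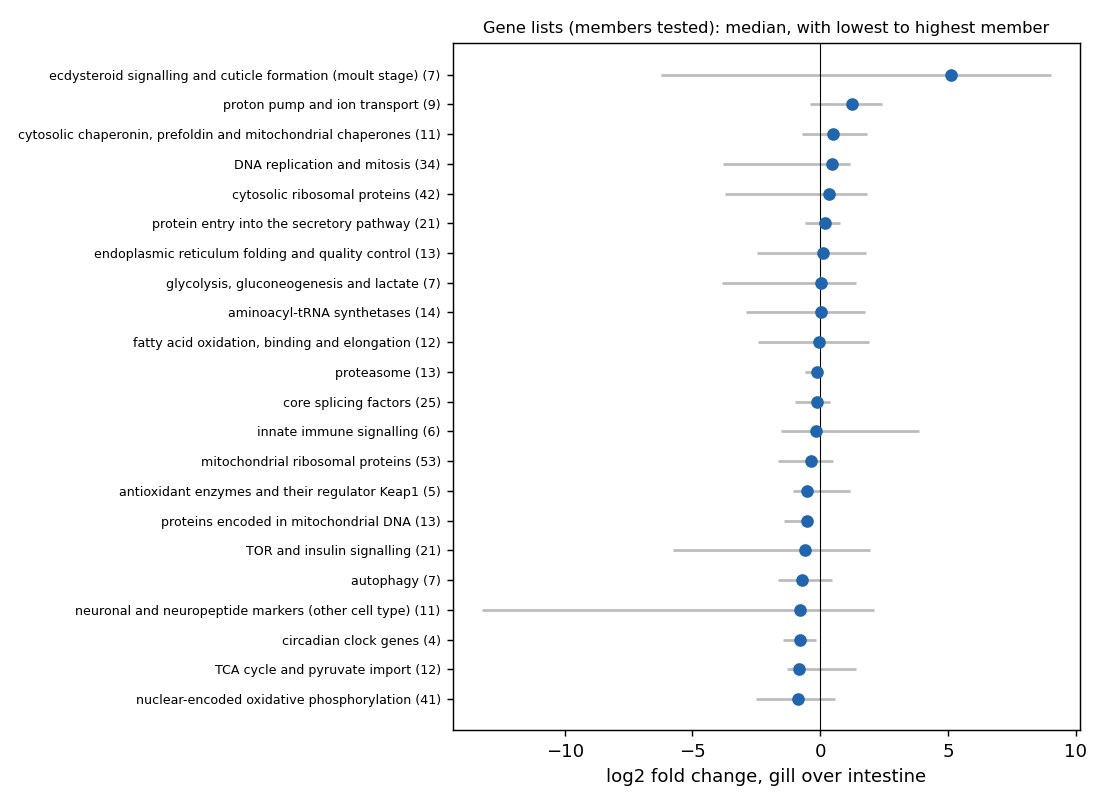
Median log2 fold change of gill over intestine (points) for each of 22 gene lists, with lines from the lowest to the highest member and the number of members tested in brackets. Nuclear oxidative phosphorylation has the lowest median at -0.87, and ecdysteroid signalling and cuticle formation the highest at 5.13.

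In total 9547 of 13854 transcripts differed between gill and intestine (4517 higher in gill and 5030 lower) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Set against other genes by camera, 2 of 22 lists passed, nuclear oxidative phosphorylation (adjusted p = 0.0003) and cytosolic ribosomal proteins (adjusted p = 0.0365), and each had adjusted p = 0.911 with an estimated correlation. Adjusted over the list alone, these had 35 lower and 1 higher, and 23 higher and 1 lower, and mitochondrially encoded proteins had 13 lower. Without gill medium 4 the count of transcripts was 9911, with 5241 higher in gill and 4670 lower.

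The main aeration question is how gill differed between low and high aeration. No transcript passed the test, and the levels of gene groups overlapped between aeration groups. All 13 mitochondrially encoded proteins had negative changes, with a median of -0.51, CYTB (cytochrome b) at -0.59 (SE 0.26) and ND5 at -0.57 (SE 0.26). Of 41 nuclear oxidative phosphorylation transcripts 39 had negative changes, with a median of -0.35, as had 12 of 12 TCA cycle and pyruvate import transcripts, with Mpc1, a mitochondrial pyruvate carrier, at -0.49 (SE 0.25). DNA replication and mitosis genes had positive changes in 33 of 34, with a median of 0.56, PolA1 (DNA polymerase alpha) at 1.0 (SE 0.49) and Mcm10 at 1.39 (SE 0.74).

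Of 22 gene lists camera called 11 for gill at low against high aeration, 10 lower and 1 higher. None of the 11 was called with the correlation between genes taken from the data, where adjusted p = 0.53 with an estimated correlation was the smallest, for mitochondrially encoded proteins and for the cuticle list. The fry test called 0 of 22 lists, with a smallest adjusted p of 0.693. The lower ones were mitochondrially encoded proteins (adjusted p = 3.1e-09), nuclear oxidative phosphorylation (3.34e-09), mitochondrial ribosomal proteins (1.38e-06; median -0.38), protein entry into the secretory pathway (0.000582; -0.21), cytosolic ribosomal proteins (0.00121; -0.16), the TCA cycle (0.00178; -0.32), ecdysteroid signalling and cuticle (0.00178; -0.67), proteasome (0.0113; -0.27), ion transport (0.0285; -0.39) and fatty acid oxidation and binding (0.0387; -0.26). DNA replication and mitosis was the higher one (1.51e-05). Genes of nuclear oxidative phosphorylation moved together across libraries with an estimated correlation of 0.911, far above the preset 0.01. Glycolysis, endoplasmic reticulum folding, chaperones, antioxidant enzymes, clock, neuronal markers, autophagy, TOR and insulin, aminoacyl-tRNA synthetases, splicing and innate immune signalling were not called, with 0.16 as the smallest adjusted p.

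The mitochondrially encoded list stood at 0.832 in gill high 1 and 1.047 in high 2, against -0.244 to 0.493 in the other high libraries. Without these 2 libraries, chosen after seeing the data, its median at low against high aeration was -0.20 (adjusted p = 0.00695), and camera called 14 lists. In the fit without all 9 gill libraries that stood apart it called 13, with nuclear oxidative phosphorylation at -1.23, and replication and mitosis was not among them (median 0.20, adjusted p = 0.34), nor was the cuticle list (adjusted p = 0.0533).

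The libraries low 4 and high 5 had the lowest levels of the replication list among the 24 gill libraries (-2.686 and -2.66) and the highest levels of the cuticle list (2.134 and 2.23), and belong to different aeration groups. Without them and high 6, chosen after seeing the data, the medians became -0.70 for nuclear oxidative phosphorylation, -0.79 for ion transport, -0.65 for the TCA cycle and 0.46 for replication.

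**Figure D4:**
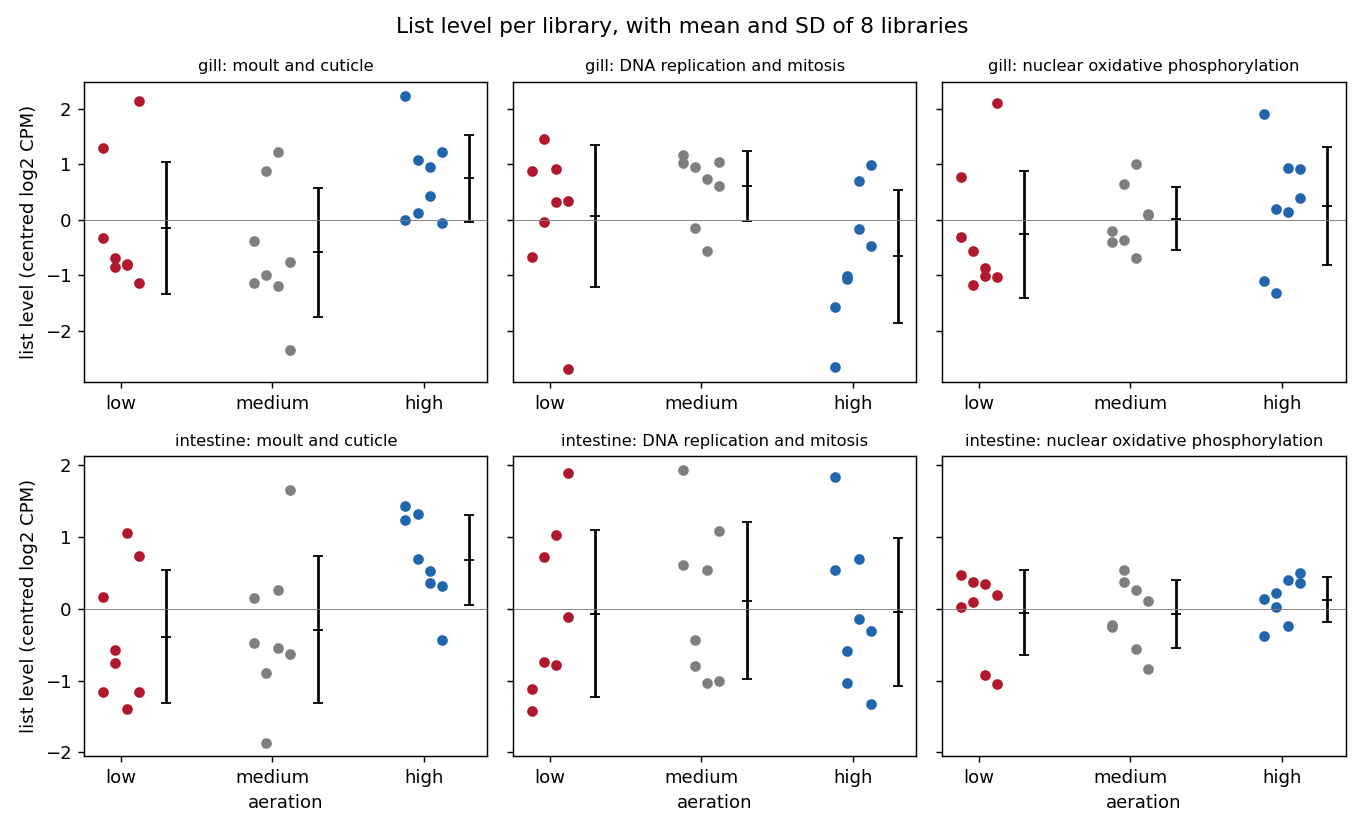
Level of 3 gene lists per library, as the mean of centred log2 CPM over members, in gill (top) and intestine (bottom) by aeration, with mean and SD of 8 libraries in black. Aeration groups overlap in each panel. In gill, low 4 and high 5 are lowest for replication (-2.686 and -2.66) and highest for moult and cuticle (2.134 and 2.23).

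Among single genes with a symbol, those with the smallest p in gill at low against high aeration were cu, bgm, aop, PRL-1 and Aldh7A1, none past the threshold. The nocturnin cu, an enzyme with a circadian rhythm in many animals, had 2.82 ± 0.82 log2 CPM at low, 3.06 ± 0.55 at medium and 4.24 ± 2.2 at high aeration, a change of -2.99 (SE 0.76, adjusted p = 0.865). The ETS-family repressor aop (anterior open) had a log2 change of -0.83 (SE 0.26, adjusted p = 0.996), with all 8 of 8 low libraries below the high median. The fatty acyl-CoA synthetase bgm (XM_027351775.1) had a log2 change of -1.44 (SE 0.44), the phosphatase PRL-1 by -1.92 (SE 0.6) and the aldehyde dehydrogenase Aldh7A1 by 0.97 (SE 0.31). In the lipid list bgm was the 1 member called lower when adjusted over the list alone, against 0 over all genes, and the other 21 lists had 0 by either. The lists gave further members short of the threshold, each at adjusted p = 0.996: the ecdysteroid enzyme phtm at -0.74 (SE 0.42), the fatty acid binding protein fabp at -1.21 (SE 0.51), the proton pump subunit Vha13 at -0.71 (SE 0.7), the mitochondrial ribosomal protein mRpL38 at -0.71 (SE 0.41), the proteasome subunit Rpn2 at -0.55 (SE 0.36), the acetylcholine receptor subunit nAChRbeta1 at 0.73 (SE 0.39) and thioredoxin reductase Trxr1 at 0.21 (SE 0.33). Trxr1 was at -0.03 without low replicate 2, and fabp at 0.07 without high 1 and high 2. Without all 9 gill libraries that stood apart, cu was at 0.14, PRL-1 at 0.72, fabp at 0.15 and Atg13 at 0.09 in place of negative values.

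edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 11769 gill transcripts at low against high aeration, with 508 at an unadjusted p under 0.05 where chance gives 588, and 368 to 1283 of them with each library left out (1283 without low 4). By limma voom this number was 2456, and without all 9 gill libraries that stood apart it was 2566. By DESeq2 it was 1081, and without the filter on low counts, which tests more transcripts, 2226. DESeq2 called 143 (12 higher and 131 lower at low aeration), or 69 on the transcripts that edgeR tested, and limma voom 1. Without gill low 2, high 1 or high 3, or without both high 1 and high 2, edgeR's count was 1. On data simulated from these libraries, with independent transcripts and shrimp, edgeR's test recovered 16% of 50 transcripts changed 2-fold, 56% of those changed 4-fold and 82% of those changed 8-fold. The transcripts nearest the threshold, without symbols, were XM_027363282.1 at 1.36 (SE 0.24) and XM_027382373.1 at -3.58 (SE 0.65), each at adjusted p = 0.0739 with 8 of 8 low libraries beyond the high median. XM_027382373.1 passed in 4 alternative settings, 1 of them with a single library left out, with changes of -3.89 to -3.58. Among these was the fit without high 1 and high 2 (adjusted p = 0.0129).

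At low against medium aeration in gill, 2 transcripts rose, both without a symbol. XM_027356531.1 was at 8.95 ± 0.74 log2 CPM at low, 6.63 ± 0.58 at medium and 7.2 ± 0.68 at high aeration, a change of 2.40 (SE 0.34, adjusted p = 0.00418, 8 of 8 low libraries above the medium median). XM_027363282.1 was at 5.33 ± 0.61, 3.88 ± 0.54 and 4.08 ± 0.16, a change of 1.48 (SE 0.24, adjusted p = 0.0182, 8 of 8). Cytosolic ribosomal proteins had negative changes in 40 of 41 members, none past the threshold, with a median of -0.46, and camera called 7 lists lower: these (adjusted p = 8.44e-22), replication (0.000369; -0.36), mitochondrial ribosomal proteins (4.52e-05; -0.32), chaperones (0.00039; -0.45), splicing (0.00874; -0.22), the TCA cycle (0.0228; -0.06) and nuclear oxidative phosphorylation (0.00731). None was called with the correlation taken from the data, where the smallest was adjusted p = 0.804 with an estimated correlation, nor by fry, with a smallest adjusted p of 0.744. Nuclear oxidative phosphorylation had a positive median of 0.06 and mean of 0.13, against the direction of its test, and a median of -0.57 without low 4, high 5 and high 6. It was not called without the 5 gill libraries that held transcripts of another library (median 0.21, adjusted p = 0.315), nor was the TCA cycle (0.12, adjusted p = 0.172), and replication was not called without low 4, high 5 and high 6 (-0.18, adjusted p = 0.168).

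Symbols with the smallest p at low against medium aeration in gill did not pass: the Hippo pathway gene kibra at 1.62 (SE 0.43), the ubiquitin protease scny at 0.76 (SE 0.23) and Rab3GAP1 at 1.67 (SE 0.53), each at adjusted p = 0.314, Sras at 0.96 (SE 0.32, adjusted p = 0.318), and mspo at -2.51 (SE 0.81, adjusted p = 0.314). The change of mspo came from gill medium 4, at 9.26 log2 CPM with the next medium library at 4.43, and was 0.16 without that library. Of the called pair, XM_027363282.1 had adjusted p = 0.0532 without gill medium 4, 0.0714 without low 7, 0.0693 without low 8, 0.0737 without medium 1, 0.0772 without medium 6 and 0.0628 without medium 8. With the replicate number as a block their adjusted p was 0.216 for XM_027356531.1 and 0.288 for XM_027363282.1, and with consecutive numbers summed 0.972 for each, so that the count of calls was 0 in both fits. It was also 0 without all 9 gill libraries that stood apart, with adjusted p = 0.0795 and 0.485, 5 without high 1 and 6 without high 1 and high 2. Counts by other tools were 130 by DESeq2, or 56 on the transcripts that edgeR tested, and 15 by limma voom, and 1074 of 11769 transcripts had an unadjusted p under 0.05 (679 with the block, 593 with consecutive numbers summed, 608 without the 5 libraries).

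At medium against high aeration in gill no transcript passed the threshold. Replication and mitosis genes had positive changes in 33 of 34, with a median of 0.96, and the ecdysteroid and cuticle list had negative changes in 6 of 6, with a median of -1.12. Camera called both (adjusted p = 4.33e-11 and 0.00129), together with higher cytosolic ribosomal proteins (5.07e-08; median 0.29) and lower mitochondrially encoded proteins (0.00135; -0.46). No list was called with the correlation taken from the data, where the smallest was adjusted p = 0.695 with an estimated correlation, for the cuticle list. The library high 5 is among the 2 with the most extreme levels of both lists in gill (replication -2.66, cuticle 2.23). Leaving out low 4, high 5 and high 6 gave medians of 0.75 for replication (adjusted p = 7.49e-08) and -0.78 for cuticle (0.00914). Adjusted over the list alone, 4 members of the lipid list, 1 of the cuticle list, 1 of ion transport and 1 of autophagy were lower at medium aeration, and the clock list had 1 higher and 1 lower, against 0 over all genes. Without gill medium 4 camera called 7 lists. Without high 1 and high 2 it called 10, and mitochondrially encoded proteins were not among them (median -0.10, adjusted p = 0.428). Without all 9 gill libraries that stood apart it called 12, and cytosolic ribosomal proteins were not among them (median 0.02, adjusted p = 0.817). PRL-1 had a log2 change of -2.46 (SE 0.61), bgm (XM_027351776.1) by -1.74 (SE 0.44), cu by -2.82 (SE 0.75), the autophagy gene Atg13 by -0.96 (SE 0.26) and the zinc finger gene noc by -1.18 (SE 0.32), each at adjusted p = 0.115. PRL-1 was at 0.41 and cu at 0.55 without all 9 gill libraries that stood apart. PRL-1, bgm, Atg13 and noc had 8 of 8 medium libraries below the high median, and cu had 5 of 8.

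edgeR called 0 of 11769 transcripts at medium against high aeration in gill, with 1837 at an unadjusted p under 0.05 where chance gives 588 (420 with surrogate variables, 1086 without all 9 gill libraries that stood apart). It rose to 4714 without the filter on low counts, which tests more transcripts. DESeq2 called 633 (97 higher and 536 lower at medium), or 455 on the transcripts that edgeR tested, and limma voom 0. Without high 3 edgeR's count was 1. A test for any difference among the 3 aeration groups called 2 in gill, XM_027356531.1 (adjusted p = 0.00335) and XM_027363282.1 (0.00769), with 1369 at an unadjusted p under 0.05 (808 with the block, 682 with consecutive numbers summed, 781 with surrogate variables). Its count was 0 without all 9 gill libraries that stood apart, 135 without gill low 4, 6 without gill high 1 and 6 without both high 1 and high 2.

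In intestine at low against high aeration no transcript passed the test. The hydroxyacid oxidase Hao, a peroxisomal enzyme, was nearest, at 1.37 ± 1.32 log2 CPM at low, 1.97 ± 0.96 at medium and -0.67 ± 0.42 at high aeration, a change of 2.64 (SE 0.51, adjusted p = 0.312, 8 of 8 low libraries above the high median). CCAP, the crustacean cardioactive peptide, was at -1.63 ± 1.22, 0.62 ± 2.22 and 1.34 ± 1.41, a change of -3.29 (SE 0.85, adjusted p = 1). CCAP belongs to the cuticle and neuronal lists, and each had 1 member lower when adjusted over the list alone, here and at low against medium aeration, against 0 over all genes. Ahcy, which breaks down S-adenosylhomocysteine, had a log2 change of -1.56 (SE 0.46), the translation factor eIF6 by -1.01 (SE 0.3) and the selenocysteine elongation factor eEFSec by 0.82 (SE 0.26). Camera called 1 list lower, nuclear oxidative phosphorylation (median -0.11, 34 of 41 negative, adjusted p = 0.0341), with adjusted p = 0.977 with an estimated correlation. Without intestine low 3, low 8, medium 3 and medium 4, chosen after seeing the data, this list was called higher (median 0.11, adjusted p = 0.00639), and 6 lists were called. The others were cytosolic ribosomal proteins (-0.37, against 0.13 with all libraries; adjusted p = 1.12e-18), replication (-0.75, against -0.05; 0.000267), the cuticle list (-2.63, against -1.56; 0.0136) and chaperones (-0.29; 0.0176) lower, and mitochondrial ribosomal proteins (0.13; 0.0345) higher.

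Further list members in intestine at low against high aeration, none past the threshold (adjusted p = 1), were UQCR-C1 of complex III at -0.41 (SE 0.29), the mitochondrial ATP8 at 0.38 (SE 0.21), Mpc1 at -0.82 (SE 0.4), mRpL38 at -0.55 (SE 0.27), Rpn2 at -0.62 (SE 0.26), the oxidative stress regulator Keap1 at -1.08 (SE 0.44), peroxiredoxin Prx6a at 0.84 (SE 0.44), mTor at 0.25 (SE 0.16), bgm (XM_027351775.1) at -0.96 (SE 0.44), the acetyl-CoA acetyltransferase Acat2 at 1.22 (SE 0.63) and the gluconeogenic fbp at -0.64 (SE 0.42). edgeR called 0 of 11645 transcripts, with 499 at an unadjusted p under 0.05 where chance gives 582 (375 to 879 with each library left out, 879 without high 3, 853 by DESeq2). Without the filter on low counts, which tests more transcripts, this number was 2680. DESeq2 called 8 and limma voom 0. In simulated data with independent transcripts and shrimp, edgeR's test recovered 22% of 50 transcripts changed 2-fold and 60% of those changed 4-fold.

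In intestine at low against medium aeration no transcript passed the test, and no list was called with an estimated correlation or by fry. Proteasome genes had positive changes in 13 of 13 (median 0.24), secretory pathway genes in 18 of 21 (0.21) and endoplasmic reticulum folding genes in 10 of 11 (0.27), while ribosomal proteins had negative changes in 39 of 40 (-0.18). Camera called these with ion transport, splicing and mitochondrially encoded proteins, 7 lists in all, 5 higher and 2 lower (adjusted p from 4.74e-10 to 0.0492), and 3 in place of 7 with consecutive numbers summed. The smallest over all lists was adjusted p = 0.354 with an estimated correlation and 0.417 by fry. Without intestine low 3, low 8, medium 3 and medium 4 5 lists were called, with proteasome at 0.20 and ribosomal proteins at -0.61, and the secretory pathway (adjusted p = 0.0714), endoplasmic reticulum folding (0.295), splicing (0.548) and mitochondrially encoded proteins (0.0714) were not. CCAP had a log2 change of -3.25 (SE 0.85), eEFSec by 0.74 (SE 0.25), sigmar by -0.55 (SE 0.21), the tRNA dihydrouridine synthase Dus2 by 0.73 (SE 0.3) and cyp33 by -0.42 (SE 0.17), each at adjusted p = 1. edgeR called 0 of 11645, with 309 at an unadjusted p under 0.05 (535 without low 3, 170 without medium 3, 864 by limma voom, 514 by DESeq2, 478 with surrogate variables). The number was 2206 without the filter on low counts, which tests more transcripts. DESeq2 called 1 and limma voom 0.

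At medium against high aeration in intestine Hao stood nearest to a call again, with a change of 2.94 (SE 0.52, adjusted p = 0.095) and 8 of 8 medium libraries above the high median. Proteasome genes had negative changes in 13 of 13 (median -0.32), as had splicing genes in 24 of 25 (-0.29) and secretory pathway genes in 18 of 21 (-0.2), and ribosomal proteins had positive changes in 39 of 40 (0.3). Camera called 8 lists, 6 lower and 2 higher, the others being nuclear oxidative phosphorylation, endoplasmic reticulum folding and aminoacyl-tRNA synthetases (lower) and mitochondrially encoded proteins (higher). Their adjusted p ran from 1.56e-05 to 0.0369, and the smallest was adjusted p = 0.478 with an estimated correlation. Without intestine low 3, low 8, medium 3 and medium 4 4 lists were called: proteasome (-0.22), secretory pathway (-0.06) and the cuticle list (-1.86) lower and ribosomal proteins (0.24) higher. Splicing (-0.16, adjusted p = 0.064) and nuclear oxidative phosphorylation (0.00, adjusted p = 0.76) were not. The translocon subunit Sec61beta had a log2 change of -0.83 (SE 0.24), the ciliary transport gene IFT57 by 1.13 (SE 0.34), eIF6 by -0.97 (SE 0.3) and Rpn2 by -0.8 (SE 0.26), each at adjusted p = 0.821. Adjusted over the list alone, 1 member of the secretory list was lower, against 0 over all genes.

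Hao passed in intestine at medium against high aeration with only these 2 groups in the fit (adjusted p = 0.0121), with surrogate variables (0.00825) and by DESeq2 (1.34e-05), and without low 3 (0.0283), low 6 (0.0476) or medium 2 (0.0473). edgeR called 0 of 11645 transcripts here, with 616 at an unadjusted p under 0.05 (1170 without high 3, 387 without medium 3, 389 without medium 4, 394 without these 2, low 3 and low 8, 1033 by DESeq2), DESeq2 called 6 and limma voom 0. The test for any difference among the 3 groups called 0 in intestine, with 452 at an unadjusted p under 0.05 (771 without high 3, 814 by limma voom, 775 by DESeq2), and DESeq2 called 2.

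Whether the difference of low against high aeration was larger or smaller in gill than in intestine was tested as an interaction, with values as gill minus intestine. Among symbols, the smallest p belonged to the nocturnin cu, at -3.12 (SE 0.82, adjusted p = 0.447). Next in order of p were Hao at -1.76 (SE 0.58), PRL-1 at -1.88 (SE 0.65), Acat2 at -2.6 (SE 0.98) and the Toll pathway gene Pli (pellino) at -0.95 (SE 0.38), none past the threshold. PRL-1 was at 0.06 by limma voom and at 0.06 without gill high 1 and high 2. It was at 0.94, and cu at 0.20, without all 9 gill libraries that stood apart. Camera called 7 of 22 lists: in gill relative to intestine, mitochondrially encoded proteins (median -0.61), mitochondrial ribosomal proteins (-0.35), cytosolic ribosomal proteins (-0.29), nuclear oxidative phosphorylation (-0.27) and the secretory pathway (-0.22) were lower, and replication (0.49) and neuronal markers (0.43) higher. None was called with the correlation taken from the data (smallest adjusted p = 0.513 with an estimated correlation). Without gill high 1 and high 2 neither higher list was called (replication 0.41, adjusted p = 0.0897; neuronal 0.41, adjusted p = 0.109), and all 9 called lists were lower. Replication was also not called without all 9 gill libraries that stood apart (adjusted p = 0.48). Neuronal markers were not called with DESeq2's size factors (adjusted p = 0.0509), without low 4, high 5 and high 6 (0.0753), without the 5 gill libraries that held transcripts of another library (0.057), without all 9 gill libraries that stood apart (0.172) or without intestine low 3, low 8, medium 3 and medium 4 (0.167). Without the latter, cytosolic ribosomal proteins were called higher (median 0.16, adjusted p = 0.00216). edgeR called 0 of 13854 transcripts, with 677 at an unadjusted p under 0.05 where chance gives 693 (251 with gill and intestine of the same number paired by a block, 1472 by limma voom, 1556 without all 9 gill libraries that stood apart), DESeq2 called 242, or 202 on the transcripts that edgeR tested, and limma voom 0.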

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

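All tests of explanations below were chosen after the results were seen. The counts of regroupings for calls were planned, and those for small unadjusted p or with consecutive numbers kept together were not. They were run on 100 regroupings of the libraries, the real one included. Values were looked for in which the highest or lowest of 8 libraries lay far from the rest (gap over range above 0.526). Chance gives about 15.5 such groups in 309, and 22 were found, in 16 libraries. Gill medium 4 had 5 of them.

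Gill medium 4 had 36.9% mitochondrial counts (next 22%), a TMM factor of 0.917 (next 1.085), a level of mitochondrially encoded proteins of 0.67 (next -0.03), ND5 at 12.29 log2 CPM and mspo at 9.26. Gill low 4 had a TMM factor of 0.541 and Mcm10 at -3.01. Gill high 8 had 42549945 counts, and intestine low 7 had 18.6% mitochondrial counts. List levels far from their group were autophagy at -0.65 in gill medium 1, TOR and insulin at -0.36 in gill medium 6 and -0.41 in intestine high 3, aminoacyl-tRNA synthetases at 0.93 in gill low 5, and splicing at 0.98 in intestine high 1. Single genes far from their group in gill were cu at 1.07 in low 5, RpL36 at 10.14 in medium 8, nAChRbeta1 at -0.73 in high 1 and Sras at 2.77 in low 3. In intestine they were bgm at 3.8 in medium 6 and 0.65 in high 6, Dus2 at 0.22 in low 5 and Sec61beta at 6.86 in high 4. Lists whose difference of low against high aeration differed between gill and intestine by camera had medians, as gill minus intestine, of -0.61 (mitochondrially encoded), -0.35 (mitochondrial ribosomal), -0.29 (cytosolic ribosomal), -0.27 (nuclear oxidative phosphorylation), -0.22 (secretory), 0.49 (replication) and 0.43 (neuronal), and 0 of the 7 were called with an estimated correlation. Without gill high 1 and high 2, replication and neuronal markers were not called.

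Each of 5 gill libraries held nearly all abundant transcripts of another library. For transcripts above 50 CPM in the second library, the 0.1 percentile of the log2 ratio was -0.90 for gill medium 7 in medium 6, -0.99 for low 2 in low 1, -1.14 for intestine medium 4 in gill medium 4, -1.88 for high 4 in high 3 and -1.95 for high 5 in high 6. The median was -17.05 over 2256 ordered pairs of both tissues and -12.12 over pairs within gill. In 3 simulated gill pairs with no mixing it was -8.22 to -3.42. The number of pairs was set after seeing the values, and the next pair, gill high 7 in medium 6 with numbers 3 apart, had -2.11. All 5 pairs had label numbers at most 1 apart (permutation p = 2e-05), as had 6 of the closest 10 (permutation p = 5e-05), so RNA or reads of a neighbouring library may be a candidate explanation. Label numbers run in 12 consecutive pairs of 1 aeration level, and 3 of the 5 pairs are such pairs, so alike shrimp of 1 tank stay open for them. The reverse ratios were lower by at least 5.31, but among pairs with numbers further apart this gap reached 11.37, so it does not tell these apart. In gill medium 4, the 454 intestine transcripts correlated with intestine medium 4 at 0.98, at a median of 71.3% of its level, while its gill transcripts stood at 4.89 log2 CPM, which an intestine library under a gill label would not hold. Whether the mixing came at dissection, library making or sequencing was not tested.

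In gill low 4 and high 5, 75 transcripts took 26.105% and 27.721% of the nuclear counts. They were chosen as abundant in both and far lower in each of 21 other gill libraries, so that contrast follows from the choice. In the 21 their medians were -6.11 to -5.16 log2 CPM, the level without a count, with the highest single transcript at 3.32 to 6.9. High 6 was set aside by name in the choice, so its level is not an independent check. The 75 transcripts took 9.619% of its nuclear counts. Intestine RNA is argued against, since at most 0.001% of an intestine library's counts lay in them. RNA passed between low 4 and high 5 is argued against too, since the log2 ratio of the 2 libraries varied over these transcripts with an SD of 0.59, against 0.14 between high 6 and high 5. Moult stage may be a candidate explanation: on the ecdysteroid and cuticle list, which holds none of the 75, high 5 ranked 1 and low 4 ranked 2 of 24 gill libraries. Its member phtm did not stand out, at 8.93 log2 CPM in low 4 and 8.43 in high 5 around a gill mean of 8.56 (SD 0.89). Each other member lay above its gill mean in both. No record of moult stage was available to test it.

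Gill at medium against high aeration had 1837 transcripts at an unadjusted p under 0.05, where chance gives 588. Of 100 regroupings 3 reached it (highest other 2336), but 13 did so in the largest of the 3 comparisons (3194), 16 with consecutive numbers kept together (3941) and 32 with both (4420), so chance is not excluded. Without all 9 gill libraries that stood apart the count was 1086, and 46 of 100 removals of as many libraries per group went as low (median of the others 1159), so whether these libraries make up the excess cannot be told. With surrogate variables in the fit the count was 420, so structure among libraries beyond the aeration groups may account for the excess, although the same fit raised low against high from 508 to 918. Aeration itself stays open, as tanks were not identified.

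A count of 0 is reached by all 100 of 100 regroupings, so the regroupings decide nothing for gill at low against high (highest other 643) and medium against high (153), nor for the 4 intestine counts (41, 30, 21 and 60) and the difference between tissues (1066). Chance could not be excluded for the counts above 0 between aeration groups. In gill, 10 regroupings reached 2 at low against medium (1218) and 11 reached 2 over any difference (774). For gene lists they were 12 for 11 (13), 55 for 7 (14) and 81 for 4 (13) in gill, and 97 for 1 (10), 26 for 7 (11) and 12 for 8 (11) in intestine. Regroupings of gill that call up to 1218 transcripts, many times the real count, point to a structure of the gill libraries. By DESeq2 in 40 regroupings, 10 reached 143 (highest other 1157), 12 reached 130 (724) and 5 reached 633 (1793). For the difference between tissues the median was 0 in the 34 regroupings that kept gill medium 4 among the medium libraries, against 530 in the 65 that placed it with low or high. For gill against intestine only the real grouping, 1 of 100, reached 9547 (highest other 231), so chance is excluded.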

How the results depend on the processing

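The fits without the libraries that stand apart, DESeq2 on the transcripts that edgeR tested, and all settings of the lists for tissue contrasts, were chosen after seeing the data. Between aeration groups, counts of calls moved most with DESeq2 (edgeR's count in brackets), whose own filter also tested more transcripts. In gill it called 143 (0) at low against high, 130 (2) at low against medium, 633 (0) at medium against high and 257 (2) over any difference. In intestine it called 8, 1, 6 and 2, each against 0 by edgeR, and for the difference between tissues 242 (0). On the transcripts that edgeR tested DESeq2 called 69, 56, 455 and 235 in gill, 7, 0, 3 and 5 in intestine, and 202 for the difference between tissues. Limma voom called 1 at low against high and 15 at low against medium in gill. With only the 2 groups in the fit there were 5 at gill low against medium and 1 at intestine medium against high. Surrogate variables gave 1 at intestine medium against high, 1 over any difference in intestine and 1 for the difference between tissues. In gill low against medium and over any difference, the count of 2 was 0 with summed pairs of consecutive numbers, 1 without the 5 libraries holding transcripts of another library and 1 without low 4, high 5 and high 6. Low against medium was also 1 without gill medium 4. Without all 9 gill libraries that stood apart both counts of 2 were 0. Without gill high 1 and high 2 the counts were 1 at low against high, 6 at low against medium and 6 over any difference. The cause was not tested.

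With the replicate number as a block, gill low against medium and any difference had 0 calls in place of 2, and no other count of adjusted calls moved past 1.5 times. For the difference between tissues the block instead paired gill and intestine of the same aeration group and number. With it 251 transcripts in place of 677 had an unadjusted p under 0.05. Correlations below are of deviations from group means. Same-numbered gill libraries of 2 aeration groups correlated at -0.36 to 0.65 (mean 0.10, 11 of 24 pairs above 0.1), against a mean of -0.01 for other pairs across groups. In intestine they correlated at -0.45 to 0.59 (mean 0.05, against -0.01). Whether the numbers link libraries across aeration groups within a tissue was not tested. Gill and intestine of the same number correlated at -0.01 to 0.15, and 12 of 24 gill libraries were closest to their own number, where chance gives 3, a hint from the data only. Consecutive gill numbers correlated at a mean of 0.13 against -0.17 for other pairs (permutation p = 0.00488), and in intestine at -0.05 against -0.15 (permutation p = 0.141).

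Leaving out each library in turn gave 0 to 1 calls at gill low against high, 1 to 5 at low against medium, 0 to 1 at medium against high and 2 to 135 over any difference (135 without low 4), and 0 to 1 at intestine medium against high. The other aeration counts in intestine and the difference between tissues stayed at 0. Without the filter on low counts, which tests more transcripts, numbers at an unadjusted p under 0.05 were larger throughout. They reached 3995 at low against medium and 4991 over any difference in gill. In intestine they were 2389 at medium against high and 3195 over any difference, and 1486 for the difference between tissues. Gill against intestine ran from 9526 to 11928 over all settings (11928 without the filter, 10826 by DESeq2), and shared 8720 to 9373 calls with the 9547.

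For gene lists, an estimated correlation and fry each gave 0 for all 6 comparisons between aeration groups and for the difference between tissues. For gill against intestine the estimated correlation gave 0 and fry 15 in place of 2, and 4 were called without gill low 4, high 5 and high 6 and 4 without all 9. Summed pairs gave 3 in place of 7 at intestine low against medium and 5 in place of 8 at medium against high. Gill medium against high had 7 in place of 4 without gill medium 4, 10 without high 1 and high 2 and 12 without all 9, which also gave 11 in place of 7 at low against medium and 12 in place of 7 for the difference between tissues. Without intestine low 3, low 8, medium 3 and medium 4 intestine had 6 in place of 1 at low against high and 4 in place of 8 at medium against high. The median of all transcripts for gill against intestine was -0.03, 0.06 with DESeq2's size factors and 0.12 without gill medium 4.

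Reversed values of single genes were PRL-1 in the difference between tissues by limma voom (0.06) and without gill high 1 and high 2 (0.06), fabp in gill low against high without the same libraries (0.07), Trxr1 in gill low against high without low replicate 2 (-0.03, range -0.03 to 0.43 with each library left out), and mspo in gill low against medium by DESeq2 (0.13, and 0.13 on the transcripts that edgeR tested), by limma voom (0.00), without the 5 libraries (0.32) and without gill medium 4 (0.16, range -2.71 to 0.16). Without all 9 gill libraries they were PRL-1 (0.72), cu (0.14), fabp (0.15) and Atg13 (0.09) at low against high, mspo (0.27) at low against medium, PRL-1 (0.41) and cu (0.55) at medium against high, and PRL-1 (0.94) and cu (0.20) in the difference between tissues. Without the 4 intestine libraries Prx6a was at -0.07 at low against high. Of the other values of named transcripts under an alternative, 4432 kept direction and side of the threshold, 38 passed it where the reported value had not and 22 no longer did. In gill data simulated at the depth and spread of these libraries, but with independent transcripts and shrimp, 16% of transcripts changed 2-fold were recovered. The effect of depth alone was not tested.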

Other observations

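All tests below were chosen after the results were seen. List levels were taken here as deviations from the mean of their aeration group. Across the 24 gill libraries, the level of the ecdysteroid and cuticle list went with that of nuclear oxidative phosphorylation (r = 0.81, permutation p = 1e-04, the smallest the permutations can give, adjusted over 6 relations p = 2e-04; Spearman's rho = 0.72) and against that of replication and mitosis (r = -0.70, permutation p = 3e-04, adjusted p = 0.00045; rho = -0.46, permutation p = 0.029). Without the 2 libraries farthest from the median on the cuticle list, r was 0.72 and -0.53. In intestine the signs were opposite: the cuticle list went with replication (r = 0.60, permutation p = 0.0036, adjusted p = 0.00432; rho = 0.54; 0.56 without 2) and against oxidative phosphorylation (r = -0.85, permutation p = 1e-04; rho = -0.81; -0.78 without 2). The cuticle list did not hold the same transcripts in both tissues: CCAP was among its 6 tested members in intestine but not in gill. The signs are thus not those of 1 fixed set, and whether the relations differ between tissues was not tested. Some transcripts of the full list were scarce in intestine, with at most 1164 counts for phtm and 35 for Cht6. The 371 gill transcripts had medians of -1.44 in intestine high 1 and medium 5 and -2.89 in high 5, against a lowest of -5.64. Whether gill transcripts in such libraries shape the intestine relations was not tested. The intestine relations were not rerun without the libraries that stood apart on the first component. Replication and oxidative phosphorylation went against each other in intestine (r = -0.79, permutation p = 1e-04; rho = -0.75; -0.71 without 2). In gill this relation (r = -0.54, permutation p = 0.0222; rho = -0.25, permutation p = 0.273) was -0.09 without 2 libraries and rests on them. Levels within a library share its scaling, so relations between lists are not independent of composition.

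Between gill and intestine of the same number, 0 of 22 list levels correlated past the threshold. The closest was fatty acid oxidation and binding, with r = 0.55 (permutation p = 0.0157, adjusted p = 0.345) and 0.46 without 2 libraries.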
